A study of Homo sapiens with 10 samples.

How the data were processed

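Poly(A) RNA of primary human aortic smooth muscle cells, the contractile cells of the arterial wall, was sequenced in 10 libraries. Per the labels' protocols, cells received 25 nM siRNA overnight, grew for 24 h, were starved overnight and were then treated for 24 h with vehicle or with 4 ng/ml interleukin-1β (IL-1β), an inflammatory cytokine. The libraries were made with a strand-marking poly(A) kit and read as single ends of 100 nt, per the labels' protocols. The siRNAs were a control, siKILN1, siKILN2 and a mixture, the last 3 directed at the long non-coding RNA KILN.

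The deposited table used for every test holds the authors' raw counts of reads per gene, under gene symbols. STAR 2.7.0f, Subread 1.6.4, featureCounts and DESeq2 1.22.1 are named per the submitters' processing notes, which give no role or order. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so no coordinates are printed, and genes that overlap or lie antisense to another gene are uncertain. A second deposited table holds the signal that the authors obtained by dividing the counts by 1 factor per library. The ratio of both tables was constant within each library, and that table entered no test. Both tables have 59087 rows, and each of the 10 columns was matched to its sample by name.

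The libraries were grouped by siRNA (control or KILN) and treatment into 4 arms. Each control arm had 2 libraries. Each knockdown arm had 3, with 1 library per reagent, so the reagents were tested together and the spread within the arm includes differences between reagents. Nothing in the labels says that libraries came from separate cultures, and p-values then measure the spread between these samples, which may be technical. Counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, leaving 16290, and libraries were scaled by TMM. One quasi-likelihood fit of the 4 arms to all 10 libraries had 6 residual degrees of freedom. Tests were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors were derived from the fitted log2 fold change and the F statistic. Levels are CPM (counts scaled to a common library size) computed from the deposited counts with TMM-scaled library sizes, as mean ± SD over the libraries of an arm. Single libraries were compared as log2 CPM with a prior count of 2. A gene at 0 in an arm was given a bound from 3 counts over that arm, which covers counting error only.

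A set of 20 gene lists was tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01. An estimated correlation and fry were run beside it. Of 417 list genes, 414 had a row under the name in the list and 379 were tested. MCAM, OAS1 and RIGI had no row under that name and are not analysed here. These lists, the tests of the comparisons, the rule for named genes and all but 2 kinds of alternatives were fixed before the data were examined. Further tests of explanations were chosen later, as stated where they are given. The rule took genes with a symbol, past the threshold, with a mean of at least 2 CPM and with every library of one arm above every library of the other. It took up to 12 per direction for the IL-1β response in control cells and for the knockdown under IL-1β, up to 6 for the knockdown in vehicle and averaged over treatments, and 5 for the interaction without the condition on overlap. For the average, the condition was applied within each treatment. Places left open were filled from the fit with label-number set as a block. Up to 4 members per list with the smallest p, and CXCL8, IL6, MRTFA, USP10, ACTA2, MYH11 and GAPDH, were added. Clone-based names, carried by 1684 of the tested genes, were not taken as symbols. Genes on the Y chromosome and X-inactivation transcripts are not reported here.

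The labels number the libraries, and the numbers fall into 2 sets: the first holds 6 libraries (control, siKILN1 and the mixture) and the second 4 (control and siKILN2). The labels do not say what the sets are. Differences between the sets correlated across genes, with r = 0.36 between vehicle and IL-1β control libraries, 0.47 between vehicle and IL-1β knockdown libraries, 0.25 between control and knockdown in vehicle and 0.33 between control and knockdown under IL-1β. The set itself passed the threshold for 76 genes. In the knockdown libraries the sets also differ in reagent, since siKILN2 occurs only in the second. The correlations that use knockdown libraries and the 76 genes therefore mix set and reagent. A fit with the set as a block was read beside the main one. That block can also take differences of siKILN2 from the other reagents out of the spread.

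Pairs of libraries of the same arm differed far beyond sampling noise, with a chi-square per degree of freedom between 34.3 and 101.4, so none was treated as a repeat of another. The fit was tested on simulated counts with 200 changed genes per comparison. For the IL-1β response in control cells it recovered 65.2% of 4-fold changes and 11.9% of 2-fold changes among 15932 genes, and for the knockdown under IL-1β it recovered 60.6% and 2.99% among 15896. For the interaction it recovered 40.9% of 4-fold and 1.49% of 2-fold changes among 15925 genes. Alternatives covered scaling, filtering, DESeq2 1.42.0, the set block, the libraries entering the fit, leaving out each library and a fold minimum. Library-size scaling and a correction for GC content and length, for the 98.2% of tested genes found in GENCODE v29, were added after the data were seen. Neighbouring genes were taken from the order of genes in RefSeq on GRCh38.p14.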

Results

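Gene expression was measured in primary human aortic smooth muscle cells that received a control siRNA or siRNA against the long non-coding RNA KILN and were then treated with vehicle or IL-1β. There were 2 control libraries and 3 knockdown libraries per treatment, the latter from siKILN1, siKILN2 and a mixture labelled as both, with 1 library each. Total counts ranged from 17267355 in control vehicle replicate 2 to 22877149 in control vehicle replicate 1. The first principal component of log2 CPM held 38.7% of the variance and separated the vehicle from the IL-1β libraries. The second held 20.5% and separated control from KILN siRNA libraries.

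The targeted RNA was examined first. No row carries the name KILN or INKILN, so its level is not analysed here and the knockdown was not checked. The RefSeq gene table places INKILN beside CXCL8 and overlapping another locus, listed as AC112518.1, whose row held at most 1 count in any library and 2 counts over all 10. Because that overlap is uncertain, the row does not measure the target. Knockdown below therefore means libraries labelled with a KILN siRNA.

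The comparison of IL-1β with vehicle in control siRNA cells gives the response against which the knockdown is read. IL-1β raised inflammatory mediators by large factors. CXCL8, a neutrophil-attracting chemokine, rose from 232.0 ± 20.6 to 7140 ± 4193 CPM (SD, n = 2 per arm), a log2 fold change of 4.94 ± 0.54 (SE, adjusted p = 0.00212). IL6 rose from 401.8 ± 19.4 to 8470 ± 4527 CPM (SD, n = 2, log2 fold change 4.40 ± 0.49, adjusted p = 0.00212). In all, 761 genes were higher and 577 lower of 16290 tested. Among the genes with the largest rises were the chemokines CCL8 (log2 fold change 8.45), CCL3 and CXCL5 (7.15), and the cytokines IL11 (7.30), IL23A (6.95) and CSF3 (6.83), the granulocyte growth factor. The collagenase gene MMP13 (7.24), the ammonium transporter gene RHCG (6.61) and LRRC55 (6.47) also rose. CCL3 went from 0.0513 to 51.3 CPM and CPXM1 from 0.0732 to 60.2 CPM. MMP12, a macrophage elastase, and LBP, a lipopolysaccharide-binding protein, had no count in the control vehicle libraries and were at least 143.9-fold and at least 151.7-fold higher with IL-1β. Among genes taken by the naming rule, the largest falls were those of the alcohol dehydrogenase gene ADH1B (log2 fold change -6.75), the urea transporter gene SLC14A1 (-5.91), AKR1B10 (-5.83), GAS6-AS1 (-4.43), NHSL2 (-4.24), ARPP21 (-3.66), ASPA (-3.66), INSYN2A (-3.65), the thrombin receptor gene F2R (-3.56), AK5 (-3.46), SIGLEC15 (-3.45) and KY (-3.41). GAS6-AS1 is an antisense gene and therefore uncertain. GAPDH, a glycolytic enzyme gene, stood at 2648 ± 56.0 and 3287 ± 489 CPM (SD, n = 2, log2 fold change 0.31, adjusted p = 0.469). Groups did not overlap for 56.1% of genes, where chance gives 33.3%. The count of 1338 genes became 2181 with the label-number set as a block, 110 without control IL-1β replicate 1 and 197 without control vehicle replicate 2. It was 276 in a fit of the control libraries alone and 374 with the spread taken from control libraries only. With library-size scaling, which lowers the median gene by 0.19 on the log2 scale, 547 genes were higher and 956 lower.

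**Figure D1:**
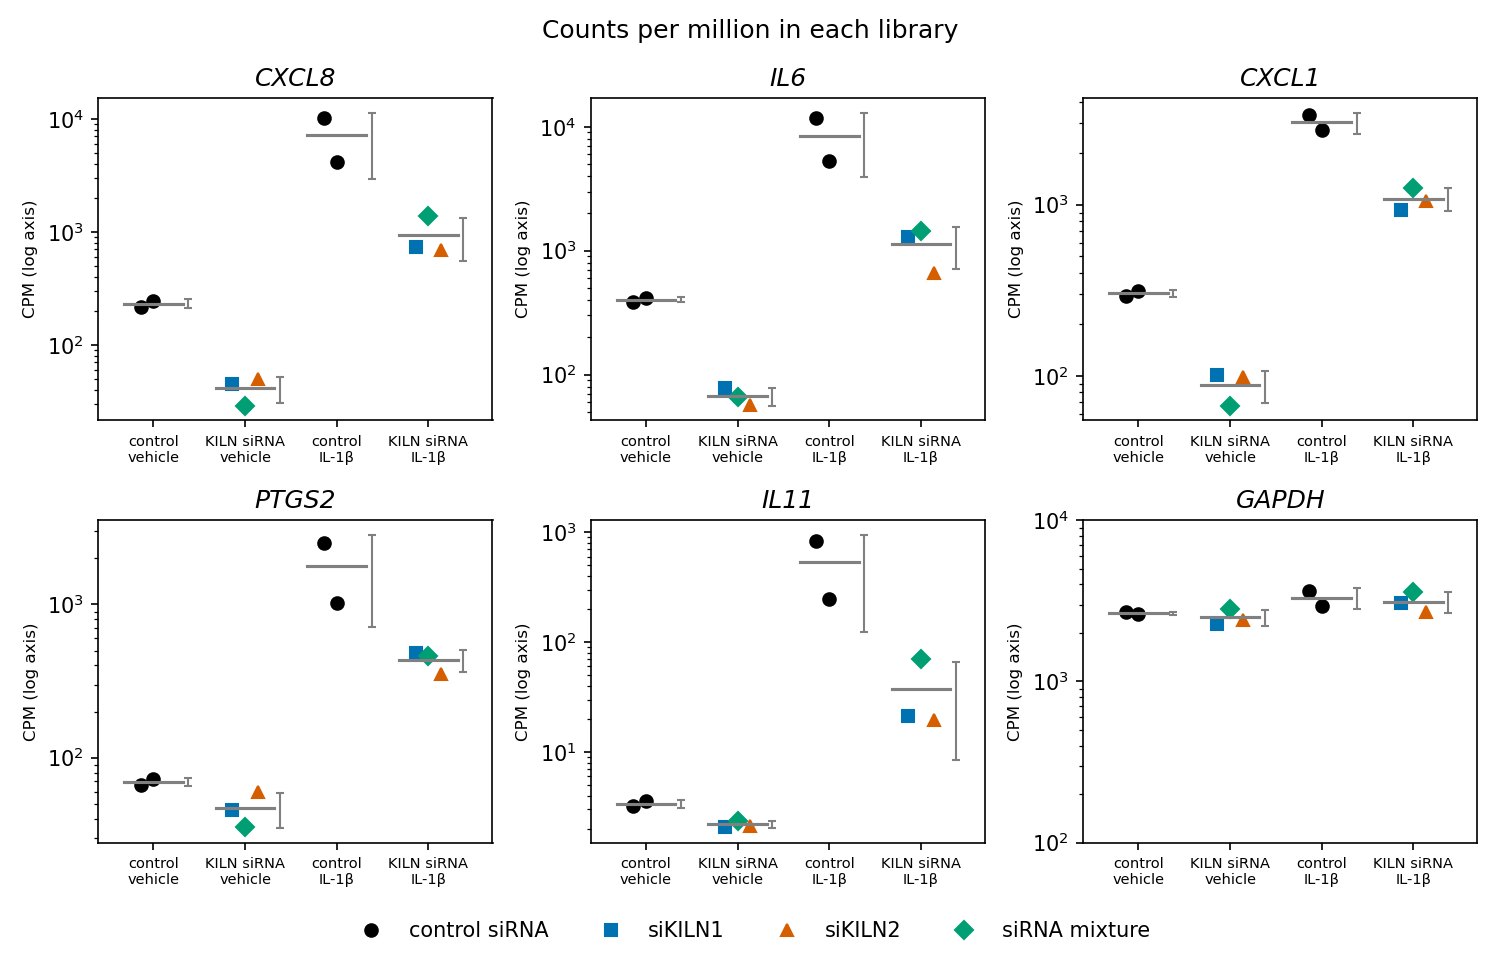
CPM on a log axis for 6 genes in each of the 10 libraries, by siRNA and treatment; grey lines are arm means and grey bars the SD. Every knockdown library lay below both control libraries of its treatment for CXCL8, IL6, CXCL1, PTGS2 and IL11, while GAPDH arms overlapped.

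The chemokine list was the most strongly shifted by IL-1β: 13 of 17 measured members rose and none fell (14 adjusted over the list alone, camera adjusted p = 3.18e-28, adjusted p = 0.0294 with an estimated correlation), with CCL20 at a log2 fold change of 5.45 and CXCL1 at 3.31. Of 21 cytokines, 9 rose and none fell (12 and 1 adjusted over the list alone). Of 24 NF-κB subunits, inhibitors and feedback genes, 8 rose (18 adjusted over the list alone), among them BIRC3 (2.83), TNIP3 (3.09), ZC3H12A (2.44) and IRAK3 (1.16). Adhesion molecules held 4 rising genes of 13 (5 adjusted over the list alone), with SELE at 3.04, ICAM1 at 2.12 and CD44 at 1.07. Proteases and inhibitors held 8 rising and 1 falling gene of 23 (11 and 3 adjusted over the list alone), with ADAMTS9 at 4.46, ADAMTS5 at 2.38 and MMP11 at -1.88. A list of prostanoid and oxidative genes, called the prostanoid list or prostanoid genes below, also holds NOS2, SOD2, HMOX1 and GCH1. It held 3 rising genes of 14 (7 adjusted over the list alone), namely PTGS2 (4.68), the inducible cyclooxygenase, PTGES (3.95) and GCH1 (2.40). Hypoxia and glycolysis genes held 6 rising of 22 (10 adjusted over the list alone, with CA9 at 3.09 and VEGFA at 1.93). Unfolded protein and stress genes held 5 rising of 21 (9 adjusted over the list alone, with ATF3 at 2.47 and HSPA5 at 1.06), and interferon-stimulated genes 2 of 33 (2 adjusted over the list alone, GBP1 1.68 and USP18 1.20). Mitotic and replication genes held 6 falling of 30 (13 adjusted over the list alone, with CCNB2 at -2.27 and MCM2 at -2.12). These 10 lists passed camera, with adjusted p from 3.18e-28 to 0.00064. With an estimated correlation only the chemokines did, and the adjusted p of the other lists that had passed ranged from 0.129 to 0.279. Lists that did not pass were contractile (adjusted p = 0.868), MRTF and SRF target (0.919), structural matrix (0.904), TGF-β target (0.186), p53 target (0.0588), cholesterol (0.986), IL-1 receptor pathway (0.252), endothelial marker (0.543), fibroblast marker (0.396) and leukocyte marker (0.0873) genes. Within them, 2 of 27 structural matrix genes (2 adjusted over the list alone) and 1 gene each of the endothelial (1 higher and 2 lower adjusted over the list alone), IL-1 receptor (1), MRTF and SRF (1 higher and 1 lower) and TGF-β (1) lists rose. Falling were 3 of 16 p53 targets (3 lower and 1 higher adjusted over the list alone) and 1 gene each of the cholesterol (1), fibroblast (2) and contractile (0) lists, and no leukocyte marker passed. With the set as a block, 12 interferon-stimulated, 14 NF-κB, 7 prostanoid and 3 IL-1 receptor pathway genes rose, 12 cytokines rose and 1 fell, 10 mitotic genes and 3 proteases fell, and other lists changed by at most 1 gene per direction or within 1.5 times. ACTA2, smooth muscle actin, was the contractile gene that fell (log2 fold change -1.33, adjusted p = 0.0382), and MYH11, smooth muscle myosin, was at 1.14 CPM in vehicle and 8.74 CPM with IL-1β (adjusted p = 0.0753).

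The comparison of KILN siRNA with control siRNA under IL-1β addresses what the targeted RNA contributes to the inflamed state. CXCL8 was 7.67-fold lower in the knockdown libraries, at 930.8 ± 383.4 CPM (SD, n = 3) against 7140 ± 4193 (SD, n = 2, adjusted p = 0.0168), and lay below both controls in 3 of 3 libraries. IL6 was 7.52-fold lower, at 1127 ± 412.6 CPM (SD, n = 3, adjusted p = 0.016). RCAN1, an inhibitor of calcineurin, had the smallest adjusted p (0.00324) and fell from 549.8 to 62.5 ± 5.82 CPM (SD, n = 3, log2 fold change -3.14 ± 0.26). In all, 57 genes were higher and 110 lower. Among the largest falls were those of LBP (log2 fold change -5.83), IL23A (-5.71), the atypical chemokine receptor gene ACKR3 (-4.12), RBM24 (-4.09), the oxidised-LDL receptor gene OLR1 (-4.03), the orphan nuclear receptor genes NR4A3 (-3.99) and NR4A2 (-3.69), CPXM1 (-3.90), IL11 (-3.85) and IGFBP4 (-3.31). Among genes taken by the naming rule, the largest rises were those of INSYN2A (log2 fold change 3.98), the chemokine receptor gene CCR1 (3.79), GAS6-AS1 (3.25), SLC14A1 (3.18), CALCRL (2.66), CAMK2B (2.64), LRRC6 (2.39), the G-protein subunit gene GNG2 (2.29), CNIH3 (2.27), C17orf97 (2.27), RGS17 (2.26) and DRC3 (2.16). GAPDH (-0.08, adjusted p = 0.903), USP10 (-0.05, adjusted p = 0.92), MRTFA (-0.12, adjusted p = 0.879) and ACTA2 (0.38, adjusted p = 0.59) did not pass. MYH11 stood at 8.74 CPM in control and 0.907 CPM in knockdown cells (adjusted p = 0.08). Groups did not overlap for 32.2% of genes, where chance gives 20%. The count of 167 rests on single libraries: it was 6 without control IL-1β replicate 1, 92 without control IL-1β replicate 2, 7 without the siKILN1 and 27 without the siKILN2 IL-1β library, 280 without the mixture IL-1β library, and 69 and 73 without the siKILN1 and siKILN2 vehicle libraries. It was 590 with the set as a block, 16 with the IL-1β libraries alone and 5 with the spread taken from control libraries only, and 588 without both mixture libraries. Library-size scaling, with which the median gene stood at 0.26 rather than 0.02 on the log2 scale, gave 157 higher and 93 lower.

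Of the 17 chemokines, 3 fell under IL-1β with knockdown (8 adjusted over the list alone, camera adjusted p = 2.28e-12, adjusted p = 0.116 with an estimated correlation), namely CXCL8, CCL20 (log2 fold change -2.45) and CXCL1 (-1.48). Of 21 cytokines, 3 fell (5 adjusted over the list alone, adjusted p = 2.19e-07, and 0.158 with an estimated correlation), namely IL6, IL11 and IL23A. Of 24 NF-κB genes, 3 fell (9 adjusted over the list alone, adjusted p = 2.51e-11, and 0.236 with an estimated correlation), namely TNFAIP6 (-2.44), BIRC3 (-1.81) and TNFAIP3 (-1.52), a feedback inhibitor, and all 24 had a negative log2 fold change. The prostanoid list held 2 falling genes of 14 (4 adjusted over the list alone), PTGES (-2.46) and PTGS2 (-2.04). The stress list held 2 of 21 (4 adjusted over the list alone), DNAJB9 (-1.69) and MANF (-1.04), both genes of the endoplasmic reticulum. Adhesion molecules held 1 of 13 (4 adjusted over the list alone), ALCAM (-1.50). No member passed over all genes in the protease (4 fell and 2 rose adjusted over the list alone), MRTF and SRF target (4 fell), contractile (3 fell), structural matrix (1 fell), fibroblast marker (1 fell) and TGF-β target (0) lists, whose medians were -0.61, -0.82, -0.60, -0.41, -0.61 and -0.39. All 12 lists passed camera as lower, the weakest being the TGF-β targets (adjusted p = 0.0497), and none did with an estimated correlation (adjusted p from 0.116 to 0.474). With the set as a block, 7 chemokines, 5 cytokines, 6 NF-κB, 4 prostanoid, 4 stress, 2 adhesion and 2 MRTF and SRF target genes fell, 3 proteases fell and 2 rose, and the other lists held at most 1 gene per direction. Mitotic (adjusted p = 0.926), hypoxia (0.901), interferon (0.646), cholesterol (0.422), p53 target (0.117), IL-1 receptor pathway (0.315), endothelial (0.678) and leukocyte marker (0.292) lists did not pass, and none of their genes did in the fit without the block, also when adjusted over the list alone.

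**Figure D2:**
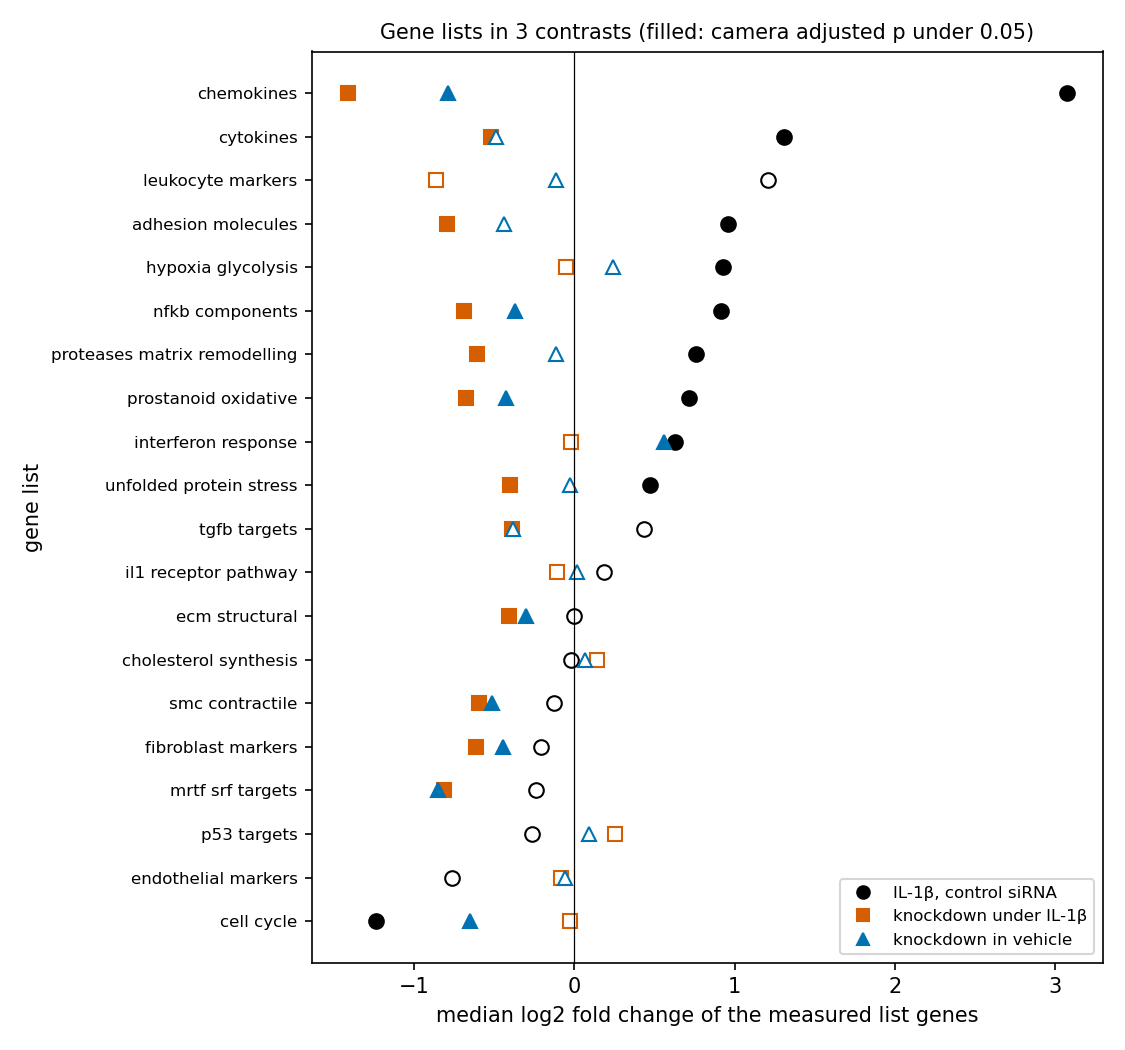
Median log2 fold change of the measured genes of each list (horizontal axis) for the IL-1β response, the knockdown under IL-1β and the knockdown in vehicle, where filled symbols passed camera at the preset correlation. The chemokine list had a median of 3.07 with IL-1β and of -1.41 with knockdown under IL-1β.

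Each reagent was represented by 1 library per treatment, so differences between reagents have no replicate check and no test. All 110 lowered and all 57 raised genes had the same direction with siKILN1, siKILN2 and the mixture, each against the mean of the control libraries. These genes were selected on the same libraries. Across 16290 genes, which are not independent replicates, the IL-1β differences of siKILN1 and siKILN2 correlated with r = 0.55 when each was set against the control library of its own number set and with r = 0.37 with the controls exchanged, no library being shared. In vehicle these values were 0.42 and 0.31. The mixture and siKILN2, each against the control library of its own set, gave r = 0.41 under IL-1β and 0.40 in vehicle. The mixture against the control of the other set and siKILN1 against that of its own gave 0.195 and 0.12. The log2 difference of CXCL8 under IL-1β was -3.15 with siKILN1, -3.24 with siKILN2 and -2.24 with the mixture. That of CXCL5 was -1.07, -0.16 and -1.33. The median of the MRTF and SRF targets under IL-1β was -1.001, -1.29 and -0.21.

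In vehicle, the same comparison asks whether the knockdown changes unstimulated cells. PODN, a matrix proteoglycan gene, fell from 50.6 ± 21.8 to 5.70 ± 1.49 CPM (SD, n = 2 and 3, log2 fold change -3.15 ± 0.32, adjusted p = 0.0232). SIDT1, an RNA transport gene, rose from 0.117 to 4.41 CPM (adjusted p = 0.0323). These were the 2 genes past the threshold, with 2409 at an unadjusted p under 0.05 and 548 called by DESeq2. Neither PODN nor SIDT1 passed in a fit of the vehicle libraries alone (adjusted p = 0.0534 for both) or with the spread taken from control libraries only (adjusted p = 0.151 for both), where 2 and 4 other genes did. With the set as a block 43 genes passed, 20 higher and 23 lower. They included IL6 (log2 fold change -2.58, adjusted p = 0.0144 with the block and 0.0841 without), CXCL1 (-1.78, 0.0298 and 0.0788), PTGES (-2.48, 0.041 and 0.113), the prostaglandin synthase gene PTGDS (-2.81, 0.0497 and 0.134) and the zinc transporter gene SLC39A8 (-2.52, 0.041 and 0.0841). The higher genes included RUFY4 (4.54, 0.0279 and 0.0788), MMP13 (4.50, 0.041 and 0.137), CCR1 (4.19, 0.0439 and 0.0841), CEACAM1 (2.74, 0.0456 and 0.0841) and GLDC (2.72, 0.0497 and 0.0841). CXCL8 stood at 232.0 ± 20.6 and 41.5 ± 11.1 CPM (SD, n = 2 and 3, adjusted p = 0.0841, and 0.0513 with the block). Groups did not overlap for 32.4% of genes, where chance gives 20%. Without both mixture libraries the count was 227. Without control vehicle replicate 1 the count was 156, without the siKILN2 IL-1β library 8, without the mixture IL-1β library or control vehicle replicate 2 it was 1, and without siKILN1 vehicle, the mixture vehicle, siKILN2 vehicle or siKILN1 IL-1β it was 0.

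No list held a gene past the threshold over all genes in vehicle, and with the set as a block 6 lists held 1 gene each. Camera placed 8 lists lower: MRTF and SRF targets (5 of 22 adjusted over the list alone, adjusted p = 4.12e-08), mitotic genes (0 of 30, 2.04e-05), NF-κB genes (0 of 24, 3.19e-05), contractile genes (4 of 21, 0.000485), chemokines (5 lower and 3 higher of 17, 0.00106), structural matrix genes (6 lower and 2 higher of 27, 0.00131), fibroblast markers (0 of 13, 0.00365) and prostanoid genes (1 of 14, 0.0166). Interferon-stimulated genes were placed higher, with a median log2 fold change of 0.56 and 31 of 33 positive (0 adjusted over the list alone, adjusted p = 8.47e-09). With an estimated correlation none passed (adjusted p = 0.473 or above). Among the members, CCN2 had a log2 fold change of -3.99 (adjusted p = 0.133) and its control vehicle libraries stood at 46.7 and 725.4 CPM, TAGLN had -1.73, IFIT3 0.95 and IFI44 0.85. The remaining lists did not pass, with adjusted p of 0.0695 for TGF-β targets and 0.106 or above for the others. With the set as a block the cytokines passed as lower (adjusted p = 0.0366, and 0.106 without). Adjusted over the list alone, these held 1 lower cytokine, 1 higher protease gene, 1 higher and 1 lower gene each of the TGF-β and IL-1 receptor lists, and 2 higher and 1 lower stress gene.

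The vehicle and IL-1β comparisons share no library. Their log2 fold changes correlated across 16290 genes with r = 0.46, and with r = 0.47 with the set as a block. Of the 110 genes lowered under IL-1β, 98 had a negative value in vehicle, where 46.3% of all genes did. Of the 57 raised genes, 55 had a positive value in vehicle. The median log2 fold change of the lowered genes was -1.75 under IL-1β and -0.69 in vehicle.

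**Figure D3:**
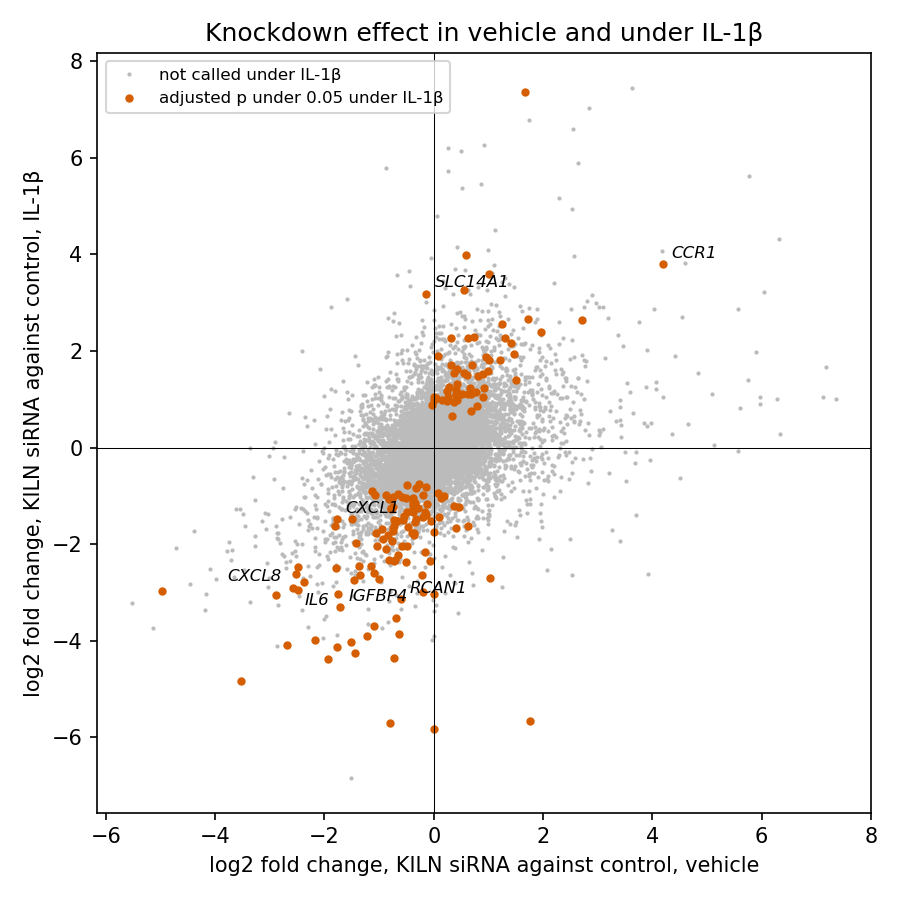
Log2 fold change of KILN siRNA against control in vehicle (horizontal axis) and under IL-1β (vertical axis) for each tested gene, where coloured points passed the threshold under IL-1β. The axes share no library, and r across genes is 0.46.

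Averaged over both treatments, 6 knockdown libraries were compared with 4 control libraries. CXCL8 was 6.55-fold lower (log2 fold change -2.71 ± 0.30, adjusted p = 0.00474) and IL6 6.72-fold lower (-2.75 ± 0.28, adjusted p = 0.00399). In all, 340 genes were higher and 509 lower, and with the set as a block 702 and 896, of which 843 were shared. Among genes taken by the naming rule, the largest falls were those of LRRC55 (log2 fold change -3.97), RBM24 (-3.39), the matricellular gene CCN2 (-3.36), NR4A3 (-3.08), the immediate early gene EGR3 (-3.06) and LMCD1 (-3.01). IL23A, which that rule did not take here, had -3.26 (adjusted p = 0.0442). By the same rule, the largest rises were those of NPTX1 (4.20), CCR1 (3.99), RUFY4 (3.61), the tachykinin gene TAC3 (3.45), SIDT1 (3.10) and ANKRD33 (2.81). CCN2 stood at 46.7 and 725.4 CPM in the control vehicle and at 18.99 and 86.25 CPM in the control IL-1β libraries, so its fold rests largely on the second control of each treatment. LRRC55 had no count in the knockdown vehicle libraries and was at least 4.61-fold lower there. GAPDH (-0.08, adjusted p = 0.8), ACTA2 (-0.07, adjusted p = 0.882) and MYH11 (-1.81, adjusted p = 0.0961) did not pass. Among the lists, NF-κB genes (6 of 24 lower, 14 with the set as a block, 12 adjusted over the list alone, adjusted p = 3.36e-10), chemokines (7 of 17, 9, 1.54e-09) and MRTF and SRF targets (6 of 22, 11, 1.54e-09) were the most strongly placed lower by camera, and no list passed with an estimated correlation (adjusted p = 0.262 or above). The count of 849 was 128 without control vehicle replicate 2, 241 and 380 without control IL-1β replicate 1 and 2, 349 and 302 without the siKILN1 vehicle and IL-1β libraries, and 270 and 385 without those of siKILN2. It was 1877 without both mixture libraries and 321 with the spread taken from control libraries only. With library-size scaling 1152 genes were higher and 371 lower.

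IL-1β also raised CXCL8 (log2 fold change 4.49 ± 0.43, adjusted p = 0.0021) and IL6 (4.07 ± 0.39, adjusted p = 0.0021) in the knockdown cells, with n = 3 per arm. There, 122 genes were higher and 32 lower, and of these 115 and 30 were also called in control cells in the same direction. Among the genes called in control cells, 97.2% had the same sign in knockdown cells. The difference between both responses was tested as an interaction, and no gene passed in edgeR with the low-count filter. There, 919 of 16290 genes had an unadjusted p under 0.05, not far above the share of 0.05 that chance gives. Without the filter edgeR called 272, and DESeq2 called 37. Adjusted over the 379 list genes alone, 0 passed. For CXCL8 the interaction was -0.46 ± 0.60 on the log2 scale (SE, adjusted p = 0.983) and for IL6 -0.33 ± 0.55 (adjusted p = 0.988), intervals that leave room for a difference in either direction. Camera placed 7 lists lower and mitotic genes higher in the interaction: interferon-stimulated genes (median -0.56; adjusted p = 2.42e-10), chemokines (0.000202), mitotic genes (0.000314), cytokines (0.000753), stress genes (0.00135), NF-κB genes (0.0134), proteases (0.0333) and adhesion molecules (0.0351), and none passed with an estimated correlation (adjusted p = 0.371 or above). A lower interaction can come from higher values in vehicle as well as from lower ones under IL-1β. The median knockdown effect of interferon-stimulated genes was 0.56 in vehicle and -0.02 under IL-1β, and that of mitotic genes -0.65 and -0.03. Among chemokines, 6 were positive and 11 negative in vehicle. CXCL10 had 2.305 in vehicle and -0.896 under IL-1β, CXCL11 2.905 and -0.037, and CCL8 1.388 and -1.581, none past the threshold. With the set as a block the adhesion molecules did not pass (adjusted p = 0.053). Adjusted over the list alone, 2 chemokines, 2 cytokines and 1 protease gene were lower. For the IL-1β response in knockdown cells, groups did not overlap for 18.5% of genes, where chance gives 10%. The count of 154 genes was 53 and 73 without the siKILN1 vehicle and IL-1β libraries, 57 and 92 without those of the mixture, 102 without siKILN2 vehicle, 26 without both mixture libraries, 15 with the spread taken from control libraries only, 333 with the set as a block and 536 with the reagent as a block.

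Genes that responded to IL-1β and genes that changed with knockdown under IL-1β were compared, with the caution that both comparisons use the control IL-1β libraries. Of the 110 lowered genes, 86 were raised by IL-1β in control cells, where independent lists would share 5.14. Of the 57 raised genes, 33 were lowered by IL-1β, where 2.02 would be shared. No gene moved in the same direction in both. The log2 differences correlated with r = -0.54 across genes, and simulated unchanged groups against the same controls gave r = -0.55. The observed covariance was -0.31 and the simulated one -0.11. Neither chance value holds both the effects and the shared libraries, and part of the excess may come from those libraries. When the response was taken from one control pair and the knockdown from the other, with no library shared, r was -0.28 and -0.43. Of the genes at least 2 log2 units higher with IL-1β, 249 of 301 (82.7%) and 270 of 317 (85.2%) were then lower with knockdown, where 48.3% and 49.99% of all genes were. Of the genes at least 2 log2 units lower with IL-1β, 61.35% of 207 and 84.6% of 91 were higher with knockdown, with medians of 0.29 and 0.935. The first pairing rests on 1 knockdown library and the second on 2.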

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

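Library-size scaling and the GC and length correction were chosen after seeing the data. Among the named genes that passed, 2096 of 2560 values over all alternatives stayed past the threshold, 464 did not and 0 changed direction; among those that did not pass, 345 of 4326 did. Genes taken by the naming rule had arms without overlap, so leaving out a library could hardly reverse their direction. The knockdown under IL-1β was less stable, with 36 named genes past the threshold. Of these, 35 were lost with the spread taken from control libraries only and 30 in a fit of the IL-1β libraries alone. Without the siKILN1 IL-1β library 32 were lost. DESeq2 size factors in edgeR, a mean CPM of at least 1 and the GC and length correction kept every count within 1.5 times. Other counts follow in the order IL-1β response in control cells (1338), knockdown under IL-1β (167), in vehicle (2) and averaged (849), IL-1β response in knockdown cells (154) and interaction (0); the cause of these shifts was not tested. The DESeq2 Wald test gave 2287, 838, 548, 1808, 652 and 37. Without a filter they were 2732, 1334, 1152, 2375, 1225 and 272. The set as a block gave 2181, 590, 43, 1598 and 333, with no change for the interaction. Fits of only the arms compared gave 276 and 16 for the first pair, with fewer libraries; such a fit was not run for the interaction. Without the mixture libraries the counts were 588, 227, 1877 and 26 for the second to the fifth. The spread from control libraries gave 374, 5, 4, 321 and 15. The reagent as a block gave 536 for the fifth. The 2-fold minimum gave 403 and library-size scaling 1523 for the fourth. Leaving out each library in turn gave 110 to 1395, 6 to 280, 0 to 156, 128 to 1161, 53 to 158 and 0 to 0; an arm left with a single control library is assumed to vary like the others. Lists past the threshold numbered 10, 12, 9 and 8 for the IL-1β response in control cells, the knockdown under IL-1β and in vehicle and the interaction, against 1, 0, 0 and 0 with an estimated correlation; fry, which does not compare lists with other genes, gave 5, 0 and 0 for the last 3. For genes of at least 10 CPM the vehicle correlation of siKILN1 and siKILN2 was 0.56 rather than 0.42 and, with controls exchanged, 0.46 rather than 0.31. The target gene had no row and its alternatives were not run. Depth was similar between libraries; with 2 control libraries per treatment, simulated 2-fold changes were mostly missed.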

Other observations

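Tests of the label-number sets, of splits within them, of single control libraries, of single siRNAs and of the genes beside the locus, and those with library-size scaling and the GC and length correction, were chosen after at least part of the results were seen. The condition that a median lie below 0 by more than its SD was added after the medians were known, and it changed the reading of the single-siRNA test only, which then stayed open.

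The mixture libraries stood partly apart from those of the single siRNAs, although the label of the mixture names both. Endothelial marker genes had a median log2 difference from control under IL-1β of 0.57 with the mixture, -0.44 with siKILN1 and -0.62 with siKILN2, and in vehicle of 0.61, -0.30 and -0.22. TGF-β targets under IL-1β had 0.03, -0.87 and -0.66, and prostanoid genes -0.23, -1.26 and -1.33. Structural matrix genes had -0.93 with siKILN2 under IL-1β, against -0.13 with siKILN1 and -0.32 with the mixture. IL1B itself, in vehicle, stood at 348.9 CPM with siKILN2, against 153.7 and 171.3 with siKILN1 and the mixture and 146.8 and 62.9 in the controls; it was chosen after its values were seen. Each value is 1 library and none was tested. The share of mitochondrial counts was 5.28 ± 1.04% in control vehicle and 3.05 ± 0.15% in control IL-1β libraries (SD, n = 2), and 4.48 ± 0.47% and 3.61 ± 0.52% in the knockdown arms (SD, n = 3).

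Splits of the samples were counted for the comparisons with at least 3 libraries per group. For the knockdown averaged over treatments, 2 of the 100 splits within treatments, the real one included, called at least the 849 genes of the real split, a share of 0.02. When libraries were exchanged only within treatment and label-number set, 2 of 36 splits did, a share of 0.0556, so with the sets respected chance is not excluded at 0.05. In both counts the highest other split called 1274 genes. It set siKILN1 and siKILN2 against the controls and the mixture, which points to a structure of the samples beyond control and KILN siRNA, whose source was not tested. With the set as a block the real comparison called 1598 genes. No other split was fitted with that block, so this count cannot be set against the 1274. For the IL-1β response in knockdown cells the real split called 154 genes and the highest other 0; 1 of 10 splits reached it, and 10 splits are too few for a share under 0.05.

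A first pattern is the lower level of inflammatory genes with knockdown under IL-1β: of the 62 tested chemokine, cytokine and NF-κB genes, 59 were below 0, with a median of -0.79. Scaling by library size left a median of -0.54 (SD 0.21 over the 3 knockdown libraries) and the GC and length correction -0.81 (SD 0.37), which argues against scaling and against those biases as the whole cause. Against the control library nearer to the knockdown the median was -0.45 (SD 0.32 over the 3 knockdown libraries), and it was negative for each of them. The pattern was thus not seen against 1 control library only. That SD leaves out the spread between the controls, against which the medians were -1.09 and -0.45. With 2 controls, a high control library therefore stays open as a cause. Whether the pattern is the effect of only 1 siRNA sequence also stays open. For siKILN1 the median was -0.39 against the control library of the other number set and -1.1 against that of its own, an SD of 0.50 between controls. For siKILN2 these medians were -1.45 and -0.85. All were negative, but -0.39 lies within that SD and each siRNA has 1 library under IL-1β. A candidate biological explanation is loss of the targeted RNA, which these data cannot separate from effects of the reagents on other transcripts, because the target has no row and each reagent 1 library per treatment.

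A second pattern is a positive correlation across genes of the knockdown effects in vehicle and under IL-1β. A difference between the label-number sets could produce it, since both treatments hold both sets. The correlation was 0.47 (0.465) with the set as a block and 0.46 without. Control and knockdown arms each hold both sets, so the block could hardly move this value. A set difference carried by only the controls or only a reagent would also remain, so the test does not decide. An effect of the KILN reagents that does not need IL-1β may account for part of the correlation and was not tested further.

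A further pattern is the lower level of some chemokine genes beside INKILN: CXCL8 and CXCL1 passed the threshold under IL-1β. The other 6 on that side did not, with CXCL3 at -2.18 (adjusted p = 0.0638), CXCL2 at -1.46 (0.11), CXCL5 at -0.80 (0.636), CXCL6 at -0.61 (0.436), PF4 at 0.02 (0.992) and PF4V1 at 0.59 (0.702). Averaged over both treatments, CXCL3 (-1.82, adjusted p = 0.0207) and CXCL6 (-1.03, 0.0437) passed as well. CXCL2 (-1.12, 0.0517), CXCL5 (-0.45, 0.639), PF4 (-0.71, 0.658) and PF4V1 (0.53, 0.645) did not. The hypothesis of an effect limited to neighbouring genes was tested on the 8 tested genes on each side in RefSeq order. Their median log2 fold change was -0.43, at the 42.0th percentile of 10000 random sets matched on the IL-1β response, whose median was -0.39. Of the 110 lowered genes among the 16290 tested, 2 were among the 16 neighbours and 108 lay elsewhere. With so few neighbours most lowered genes had to lie elsewhere, so this count does not weigh on a local effect. The 8 genes on the side away from CXCL8 ranged from -0.71 to 0.49, and the tested median pools both sides. That median therefore cannot show or exclude a local effect on CXCL8, CXCL1 or the other CXCL genes.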
